A study of Macaca fascicularis and Macaca mulatta with 24 samples.

How the data were processed

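RNA of 24 cortical samples was measured on 2-colour Agilent arrays, 1 array per sample. Per the labels, the sample RNA of each array was in Cy5 and a common reference RNA in Cy3, with no dye swap, so each ratio is sample over reference and dye bias was not tested. The 8 groups were set by treatment, hemisphere and time, with 3 animals in each. Per the file headers the arrays were of 1 design with probe coordinates on the rhesus macaque build rheMac2, whereas the labels name cynomolgus macaques, so a probe that differs from the cynomolgus sequence can read low.

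Per the file headers, the authors extracted the images with Agilent Feature Extraction 9.5.3.1 (placebo 1 h), 10.5.1.1 (placebo 6 h) and 10.7.3.1 (TatNR2B9c), while the submitters' processing notes name 10.7.3.1 alone. The deposited intensities are the mean brightness of each spot and the median of its local background in each channel, on a linear scale and not normalised, per the file headers. The processed intensities were background-subtracted and dye-normalised within each array by the same software, per the file headers. The deposited log10 ratio of each spot is that of processed Cy5 over processed Cy3, per the file headers. The deposited signal flags, set to 0 or 1 by the software per the file headers, say whether a spot was well above background, positive and significant, saturated or not uniform. The authors' series matrix holds the same log10 ratios, differing from the scanner values by at most 0.005, with a direction and scale that this comparison settles and no further centring. Its column medians (log10, arrays 1, 2 and 3) were 0.138, 0.081 and 0 for placebo left 1 h, 0.064, 0.033 and 0.175 for placebo right 1 h, 0, 0 and 0.029 for placebo left 6 h, 0.021, 0.021 and 0.01 for placebo right 6 h, 0, 0 and 0.036 for TatNR2B9c left 1 h, 0.06, 0 and 0 for TatNR2B9c left 6 h, and 0 on each TatNR2B9c right array.

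Each array held 41851 spots, of which 1417 were controls and 40434 read 20217 gene probes, with a median of 2 spots per probe. Background was corrected with limma's normexp method (offset 50) on mean signals and median backgrounds, and log2 ratios were normalised by loess within each array, with control spots at weight 0. Control spots and spots marked as not uniform were then left out, saturated spots were kept, and spots of one probe were averaged. A probe was kept if it was well above background in Cy5 on every array of at least 1 group, which left 17226 probes. A gene was read by its probe with the highest mean log2 intensity, which gave 15944 genes, 13037 of them with a symbol and 1054 with several kept probes. For 13 of 19 passing values of named genes with a further probe, all of its probes had the same sign. Gene names are those of the array files, with 6634 probes named by the newest annotation there, 9780 only by the oldest and 3803 by none, and in 1110 of 5844 probes with both the names differed. No genome or annotation was used to update them.

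Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 24 arrays with 1 mean per group, so that the 8 groups share 1 estimate of the spread of each gene. The 15 comparisons were right against left in 4 groups of animals, TatNR2B9c against placebo in 4, 6 h against 1 h in 4, and 3 interactions (treatment by hemisphere at each time, and treatment by time in right cortex). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. Differences are given in log2, with a fold where they are large. Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated one, adjusted over all 375 tests. The median of a list is that of its members' differences, and the test uses their moderated statistics. The share of probes well above background and the spread of right-left differences were compared by exact permutation tests, for which 3 against 3 arrays give p of at least 0.1. Values were handled with the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

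The comparisons, the rule for named genes, the 25 lists and the first set of alternatives were chosen before the data were examined. The lists were NMDA receptor and PSD-95 complex, AMPA, kainate and metabotropic glutamate receptors, GABA receptors, voltage-gated ion channels, immediate early genes, heat shock and chaperones, hypoxia-inducible targets, inflammatory cytokines and NF-kB targets, apoptosis and p53 targets, NRF2 and metallothioneins, endoplasmic reticulum and integrated stress response, neurotrophic factors and receptors, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, RNA polymerase II and general transcription factors, reference genes, and markers of neurons, astrocytes, oligodendrocytes, microglia and macrophages, endothelial and mural cells, neutrophils and red cells, lymphocytes, and meninges and choroid plexus. Genes were named by the 8 largest rises and falls among those that passed and whose groups did not overlap (no such condition for interactions; 4 for the treatment and time comparisons in left cortex), and by the 2 largest changes in each list. Where fewer than 5 passed, those with the 5 smallest p in each direction were taken, and GRIN2B, DLG4, NOS1, FOS, HSPA1A and IL6 in every comparison. The rule gave 213 genes, of which the text gives part, and some are not reported here.

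The alternatives were the software's processed signals, no background subtraction, median centring, quantile scaling of intensities between arrays, no filter, a filter in both channels, every probe tested by itself, the series matrix (with processed signals, the 2 processed forms), fits on only the groups compared, replicate number as a block, animal as a random block, slide or scan day as a block, each array left out, and an estimated correlation for lists. Array weights, scaling of every array to a median absolute deviation of 1, Cy5 alone and a fit without the 3 weak-reference arrays were added after seeing the data. Medians of all genes moved by over 0.1 log2 under some scalings. In right cortex, TatNR2B9c minus placebo shifted by −0.32 (1 h) and −0.15 (6 h) with processed signals, −0.77 and −0.45 with median centring, and −0.33 and −0.16 in the series matrix. In left cortex the values were −0.37 and −0.20, −0.97 and −0.53, and −0.40 and −0.21. From 1 h to 6 h the placebo right and left medians were −0.36 and −0.34, −0.80 and −0.89, and −0.36 and −0.35, and the treatment by time median was 0.19, 0.31 and 0.20. Median centring also gave −0.46 and −0.35 for time under TatNR2B9c (right and left), −0.10 for right against left in placebo at 1 h and 0.19 for treatment by hemisphere at 1 h, and Cy5 alone gave −0.12 for treatment in left cortex at 6 h and 0.12 for right against left under TatNR2B9c at 6 h.

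Right and left arrays of one treatment, time and number were taken as 1 animal, since the labels number 3 animals per group. The pairing was checked on deviations from group means, which correlated across genes at −0.71, 0.69 and −0.27 for the placebo 1 h animals, −0.20, −0.11 and −0.08 at 6 h, 0.24, 0.28 and 0.43 under TatNR2B9c at 1 h and −0.21, 0.39 and 0.52 at 6 h. Arrays of one group correlated at 0.41 to 0.97, and 0 had identical values. The correlation within a batch was 0.05 for animal, 0.03 for slide and 0.08 for scan day. Few arrays limit the precision. Simulated data had 200 of 15944 genes changed by 1 or 2 log2. In the 12 comparisons of 2 groups the fit recovered 48% to 61% and 85% to 95%. In the 3 interactions it was 26% to 34% and 77% to 81%. These and the 4 to 14 false calls need not hold for the real arrays, of which other splits gave up to 2730 genes.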

Results

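Gene expression was measured in the cerebral cortex of cynomolgus macaques after occlusion of the right middle cerebral artery, an experimental stroke that stops blood flow to part of the right cortex. Animals received placebo or 2.6 mg/kg TatNR2B9c intravenously 5 min after the occlusion. TatNR2B9c is a peptide that joins a cell-penetrating Tat segment to the end of the NMDA receptor subunit NR2B, made to part the receptor from its scaffold protein PSD-95. Cortex was taken from the ischemic right and the non-ischemic left side at 1 h or 6 h (8 groups of 3 animals, 24 arrays). All values are log2 ratios of sample RNA (Cy5) over a common reference RNA (Cy3). Right and left arrays of 1 number were read as 1 animal.

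The arrays differed in sensitivity, and mainly in the reference channel. The share of probes well above background in Cy5 was 65.2% ± 17.1 (SD, n = 3) in placebo left cortex and 75% ± 1.7 in placebo right at 1 h. At 6 h it was 87.1% ± 5.8 in placebo left and 85.3% ± 1.7 in placebo right. Under TatNR2B9c it was 58.1% ± 13.4 on the left and 64.3% ± 5.9 on the right at 1 h, and 75.9% ± 22.4 and 71.9% ± 10.3 at 6 h. In 12 comparisons of 2 groups the two-sided exact permutation p lay between 0.1, the smallest that 3 against 3 arrays can give, and 0.9, and the adjusted p between 0.3 and 0.9. In Cy3, by contrast, 15.7% to 51.7% of probes were well above background on the 6 placebo 1 h arrays, against 84.3% to 92.5% on the placebo 6 h arrays. The lowest shares were 18.0% and 15.7% on placebo left 1 h arrays 1 and 3 and 22.3% on placebo right 1 h array 3, the 3 weak-reference arrays. The SD of the log2 ratios over genes averaged 0.85 in placebo left and 0.93 in placebo right cortex at 1 h, and 1.58 and 1.64 at 6 h. Placebo 1 h, placebo 6 h and TatNR2B9c arrays were scanned and extracted as 3 separate campaigns with different software versions, so every contrast of treatments, and of times under placebo, cannot be told apart from the campaign.

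**Figure D1:**
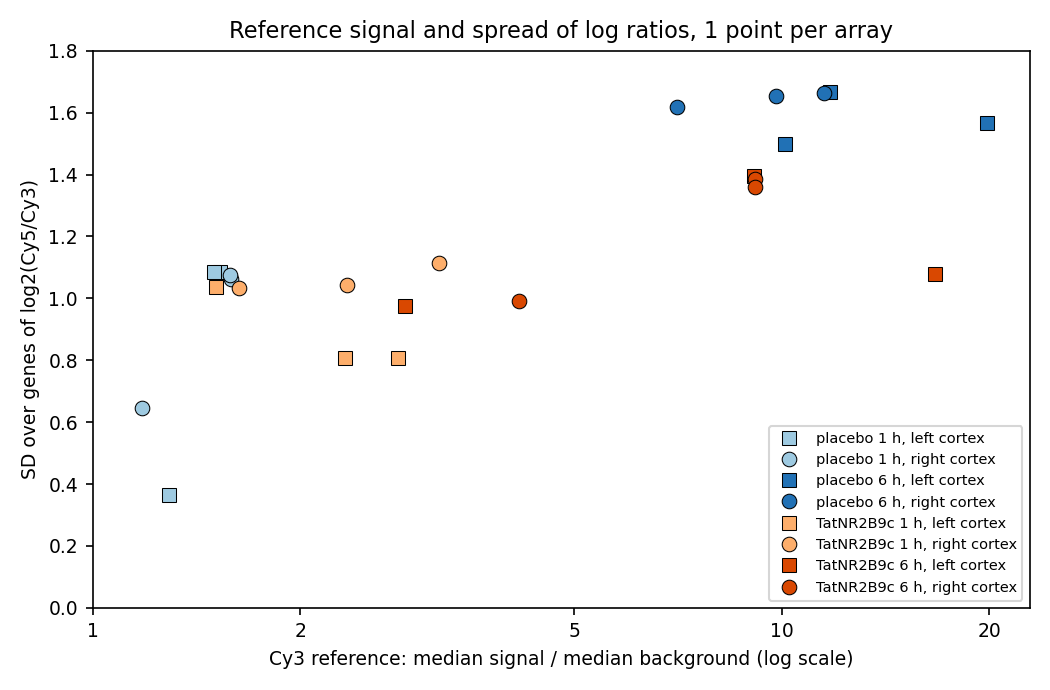
SD of the log2 ratios over genes on each of the 24 arrays (vertical axis) against the median Cy3 signal over background of that array (horizontal axis, log scale), with 1 point per array coloured by group. The 6 placebo 1 h arrays lie between 1.18 and 1.59 in Cy3 signal over background and the 6 placebo 6 h arrays between 7.05 and 19.88.

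In placebo animals, no single gene differed between the ischemic and the non-ischemic cortex at 1 h, while several gene groups shifted by small amounts. Neuron markers were higher on the right by a median log2 of 0.30, with 27 of 28 members above 0 (adjusted p = 0.00102). The NMDA receptor and PSD-95 complex (the NMDA list) was higher by 0.17, with 25 of 29 members above 0 (adjusted p = 0.00426), and voltage-gated ion channels by 0.14 (adjusted p = 0.0096). Cytosolic ribosomal proteins, the 50 measured proteins of the translation machinery, lay at −0.27 (adjusted p = 1.53e-12). No member of these lists passed over all genes or adjusted over the list alone, and the adjusted p was 0.906 with an estimated correlation for each. By limma 0 of 15944 genes passed (209 at unadjusted p under 0.05, the level of all unadjusted counts), and 3.7% of genes had groups that did not overlap (groups apart), against 10% by chance in any comparison of 3 with 3 arrays.

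These shifts depended on single arrays. Without placebo left 1 h array 1 the medians were 0.03 for neuron markers, with the direction of the test turned, 0.07 for the NMDA list and 0.03 for ion channels, and none passed. Without placebo right 1 h array 2 they were 0.04 for neuron markers (turned), 0.04 for the NMDA list and 0.05 for ion channels, none passing, and ion channels were at 0.08 without right array 1. Without placebo right 1 h array 3, the ribosomal proteins were at −0.02 (adjusted p = 0.17). Under median centring the neuron list was at −0.36, the NMDA list at −0.13 and ion channels at −0.09, and in Cy5 alone those lists and ribosomal proteins all turned. Without the 3 weak-reference arrays ribosomal proteins were at 0.17, and the NMDA list (0.10) and ion channels (0.06) did not pass. With the arrays scaled to equal spread, neuron markers (0.41) and the NMDA list (0.33) did not pass. All 6 arrays were scanned on 1 day, and day as a block left the medians as they were. With slide as a block the medians were also the same, 0 genes passed, and within slide 1 and slide 2 neuron markers were at 0.85 and −0.50, the NMDA list at 0.22 and −0.14 and ribosomal proteins at −0.03 and −0.51. Slide 2 held 1 array of each side, both of them weak-reference arrays, which is too few to test single genes.

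At 6 h after placebo again no single gene passed. Astrocyte markers were higher on the right by a median of 0.50 over 20 genes (adjusted p = 9.64e-06). In animals 1 to 3 it was 1.39, 0.74 and −0.79. Ribosomal proteins lay at −0.45 (adjusted p = 2.35e-13), immediate early genes, which neurons switch on with activity, at −0.25 over 41 genes (adjusted p = 0.0363), and microglia and macrophage markers at −0.24 over 18 genes (adjusted p = 0.0175). In each list 0 members passed over all genes or adjusted over the list alone, with an adjusted p of 0.906 with an estimated correlation. With limma 0 genes passed (615 unadjusted), and 12.8% of genes had groups apart.

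Of these lists, ribosomal proteins passed with each array left out. Astrocyte markers were at 0.07 (adjusted p = 0.394) without placebo left 6 h array 1, and microglia markers at −0.14 without left array 1, −0.24 without left array 2 and −0.29 without right array 2, all short of the threshold. Immediate early genes were at 0.07 without left array 2 and −0.01 without right array 1, where the test turned, and −0.14 without right array 2, and did not pass in Cy5 alone (−0.14) or fitted on these groups alone. Without left array 2, limma called 3 genes, 1 higher and 2 lower. With slide as a block astrocyte markers were at 0.81, ribosomal proteins at −0.26, immediate early genes at −1.47 and microglia markers at −0.30. Only slide 5 held both sides, right array 1 and left array 2, so side and animal coincide. With scan day as a block the medians were 0.57, −0.31, −1.03 and −0.31, from day 3 alone (3 right arrays and left array 2).

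Under TatNR2B9c, oligodendrocyte markers, genes of the myelin-forming glia, were higher in the ischemic than in the non-ischemic cortex at both times. Their median was 0.51 at 1 h (18 genes, adjusted p = 0.000184) and 0.72 at 6 h (adjusted p = 3.09e-06), but animal 2 lay below 0 at each time (−0.09 and −0.36). At 1 h ion channels were also higher by 0.23 (adjusted p = 0.000524), with −0.27 in the extraction software's own signals, −0.07 at equal spread, −0.21 in the series matrix and a turned test in Cy5 alone. Lymphocyte markers lay at −0.31 over 11 genes (adjusted p = 0.00102) and meningeal and choroid plexus markers at −0.50 over 16 genes (adjusted p = 0.0148). At 6 h immediate early genes were at −0.23 (adjusted p = 0.000665) and inflammatory cytokines and NF-kB targets at −0.16 over 34 genes (adjusted p = 0.00319). Heat shock proteins and chaperones were at −0.20 over 22 genes (adjusted p = 0.00268) and neutrophil and red cell markers at −0.15 over 17 genes (adjusted p = 0.00164). Again 0 members of these lists passed over all genes or adjusted over the list alone, and the adjusted p was 0.906 with an estimated correlation. At 1 h limma called 0 genes (717 unadjusted, 20% with groups apart), and 0 at 6 h (516, 2.3%).

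At 1 h the oligodendrocyte and lymphocyte lists passed with each array left out, whereas ion channels were at 0.16 (adjusted p = 0.0503) without TatNR2B9c left 1 h array 1 and meningeal markers at −0.59 (adjusted p = 0.0617) without right array 3. At equal spread oligodendrocyte (0.22), lymphocyte (−0.09) and meningeal markers (−0.13) did not pass at 1 h, nor ion channels without background subtraction (0.15), nor inflammatory genes at 6 h with no filter (−0.12). At 6 h, left array 3 carried most of the shifts, since without it oligodendrocyte markers were at 0.41 (adjusted p = 0.0794), immediate early genes at 0.09, inflammatory genes at 0.18 with the test turned and neutrophil and red cell markers at −0.11. Heat shock genes were at −0.09 without left array 1 and −0.07 without right array 3, and did not pass. Slide and scan day as blocks left every one of these medians as it was and called 0 genes. Within slides 7, 8 and 9, with 1 animal each, oligodendrocyte markers at 1 h were at 0.66, −0.09 and 0.77, lymphocyte markers at −0.50, −0.30 and −0.23 and ion channels at 0.57, 0.10 and 0.03. At 6 h slides 9 (1 animal) and 10 (2 animals) gave 1.46 and 0.35 for oligodendrocyte markers (animals 1 and 2 at 1.08 and −0.36), −0.99 and 0.03 for immediate early genes, −0.64 and 0.10 for inflammatory genes, −0.45 and −0.01 for heat shock genes and −0.23 and −0.15 for neutrophil and red cell markers.

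Whether treatment changed the right-left difference was tested as an interaction of group means, with no animal term. At 1 h ribosomal proteins were higher by 0.11 (adjusted p = 0.00138). At 6 h oligodendrocyte markers were higher by 0.76 (adjusted p = 0.00619) and AMPA, kainate and metabotropic glutamate receptors (the AMPA list) by 0.50 (adjusted p = 0.0465). Ribosomal proteins were higher by 0.45 (adjusted p = 4.25e-06) and ion channels by 0.41 (adjusted p = 0.00831), and inflammatory genes were at −0.19 (adjusted p = 0.00366), beside a median of 0.13 over all genes. Ribosomal proteins at 1 h were at −0.27 without the weak-reference arrays and −0.06 with array weights, and in Cy5 alone the direction turned for them and for glutamate receptors and ion channels at 6 h. No member passed over all genes or adjusted over the list alone, and the adjusted p was 0.906 with an estimated correlation. For single genes limma called 0 at 1 h (285 unadjusted) and 0 at 6 h (678), and 21 at 6 h without TatNR2B9c left 6 h array 2. The spread of the right-left differences over genes was 0.42 ± 0.13 (SD, n = 3 animals) under TatNR2B9c and 0.66 ± 0.36 under placebo at 1 h (two-sided exact permutation p = 0.4). At 6 h it was 0.47 ± 0.25 and 0.47 ± 0.10 (exact permutation p = 1), where 0.1 is the smallest p possible.

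The ribosomal list at 6 h passed with each array left out and with slide (0.30) or scan day (0.31) as a block. Under placebo, slide compares different animals. At 1 h slide and day blocks left the medians as they were, but ribosomal proteins were at 0.02 without TatNR2B9c left 1 h array 3, 0.01 without placebo left array 1 and −0.03 without placebo right array 3, and lost the call each time. At 6 h oligodendrocyte markers were at 0.44 without TatNR2B9c left array 3, 0.54 without TatNR2B9c right array 3, 0.55 without placebo right array 2 and 0.68 with slide as a block, none passing. Inflammatory genes were at 0.22 without TatNR2B9c left array 3, −0.08 without placebo right array 3, −0.05 with day and 0.05 with slide as a block, none passing. The AMPA list (0.24) and ion channels (0.20) did not pass with scan day as a block (0.47 and 0.41 with slide). At equal spread they were at 0.08 and 0.10 and ribosomal proteins at 0.29, and in either processed form ion channels were at 0.20, none passing, nor ribosomal proteins in Cy5 alone (0.13).

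At 1 h after the occlusion, lists of neuronal genes lay higher in the ischemic cortex of TatNR2B9c than of placebo animals, with few members past the threshold. Neuron markers were higher by a median of 0.74 (adjusted p = 3.9e-06; 2 of 28 members rose over all genes and 2 adjusted over the list alone), with −1.71 under median centring and −0.06 in Cy5 alone. GABA receptors were higher by 0.69 over 12 genes (adjusted p = 0.00227; 0 rose, 3 adjusted over the list alone), with −0.73 under median centring. Ion channels were higher by 0.48 over 43 genes (adjusted p = 2.63e-05; 2 rose). The AMPA list was higher by 0.38 over 16 genes (adjusted p = 0.039; none rose), with −0.018 at equal spread and −0.004 under median centring. The NMDA list was higher by 0.26 (adjusted p = 0.0231; 0 members rose), with −1.10 under median centring. Ribosomal proteins were higher by 0.35 (adjusted p = 1.09e-05; 3 of 50 rose, and 7 rose and 1 fell adjusted over the list alone), with −3.43 under median centring, −0.059 in Cy5 alone, −0.009 with processed signals and −0.02 in the series matrix. Lymphocyte markers lay at −0.33 (adjusted p = 0.00114), with a turned test under median centring. With an estimated correlation the adjusted p of each of these lists was 0.906. SLC8A2, a sodium-calcium exchanger of neurons, rose 5.88-fold (log2 2.56, SE 0.34, adjusted p = 0.00178), from −2.47 ± 0.35 to 0.09 ± 0.30 (SD, n = 3). SCN8A, a voltage-gated sodium channel of axons, rose by 1.86 (SE 0.30, adjusted p = 0.0061) and ZFYVE19, a protein of the abscission checkpoint, by 2.74 (SE 0.47, adjusted p = 0.0102).

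MUPCDH, a mucin-like protocadherin, fell most, by 3.00 (SE 0.33, adjusted p = 0.000241). An overlapping probe, named MUCDHL, fell by 2.46 (adjusted p = 0.00433; its further probe −0.45). The overlapping pair lies on chromosome 14 of rheMac2, at 426628 to 426687 and at 426622 to 426681. GNG4, a G protein gamma subunit of brain at 221452781 to 221452840 on chromosome 1, fell by 2.07 (SE 0.32, adjusted p = 0.00517), but was at 0.39 in Cy5 alone. In limma 60 genes were higher and 196 lower (2210 unadjusted), 50 and 119 of them by at least 2-fold, and 26.4% of genes had groups apart.

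Campaign and treatment cannot be told apart. Of the 256 genes 39.8% kept the sign in Cy5 alone, and Cy3 alone gave 3324. The count was 119 higher and 826 lower with processed signals, 104 and 843 in the series matrix, 1264 and 1452 in Cy5 alone, 26 and 28 without the 3 weak-reference arrays and 16 and 26 fitted on these groups alone. The total fell to 63 without placebo right 1 h array 1, 24 without placebo array 3, 17 without TatNR2B9c right 1 h array 1 and 65 without TatNR2B9c array 2. ZFYVE19 (2.74) did not pass without placebo array 3 or TatNR2B9c array 1 (adjusted p up to 0.0806), nor SCN8A without TatNR2B9c array 1 (0.051). GABA receptors were at 0.35 without placebo array 3, the NMDA list at 0.09 without it, and the AMPA list at 0.08 without it, 0.15 without TatNR2B9c array 1 and 0.41 without TatNR2B9c array 2, none of them passing. With scan day as a random block the count was 16 higher and 78 lower. In Cy5 alone GABA receptors were at 0.19, the AMPA list at 0.25, the NMDA list at 0.12 and lymphocyte markers at −0.28, and at equal spread neuron markers were at 0.19, GABA receptors at 0.04 and the NMDA list at 0.12, none passing. Without the weak-reference arrays the GABA, AMPA and NMDA lists were at 0.35, 0.08 and 0.09, and with array weights the last pair at 0.08 and 0.18, none passing. SCN8A was at 0.30 in either processed form and MUCDHL at −0.61 in Cy5 alone, and neither passed. Equal spread also ended the calls of SCN8A (1.59), SLC8A2 (5.47), ZFYVE19 (6.00) and MUCDHL (−2.57), and the fit on these groups alone those of MUPCDH and MUCDHL.

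At 6 h after the occlusion, 2 of 3 hemoglobin genes measured, HBB and HBQ1, were higher in the ischemic cortex of TatNR2B9c than of placebo animals. HBB, the beta chain of adult hemoglobin (rheMac2 chromosome 14, 68176263 to 68176322), rose 59.3-fold (log2 5.89, SE 0.69, adjusted p = 0.000387), from −4.42 ± 0.77 to 1.47 ± 1.00 (SD, n = 3). HBQ1, the theta chain (chromosome 20, 137265 to 137324), rose 12.5-fold (3.64, SE 0.48, adjusted p = 0.000495), although its 2 further probes were at −0.07 and 3.67. HBG1, a fetal chain, was at 0.50 (adjusted p = 0.322) and −0.17 in Cy5 alone. The list of neutrophil and red cell markers was higher by a median of 0.45 (adjusted p = 0.00268; 3 of 17 rose, and 5 rose and 1 fell adjusted over the list alone). Lymphocyte markers were higher by 0.62 (adjusted p = 0.0283; 0 rose, 4 rose and 1 fell adjusted over the list alone) and endothelial and mural cell markers by 0.52 over 21 genes (adjusted p = 0.0283; 1 rose), the latter at −0.005 under median centring. Meningeal markers were higher by 0.46 (adjusted p = 0.0096; 2 rose, 3 adjusted over the list alone) and ribosomal proteins by 0.46 (adjusted p = 0.00114; 1 rose), the last at −0.79 under median centring. The adjusted p was 0.906 with an estimated correlation for each.

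**Figure D2:**
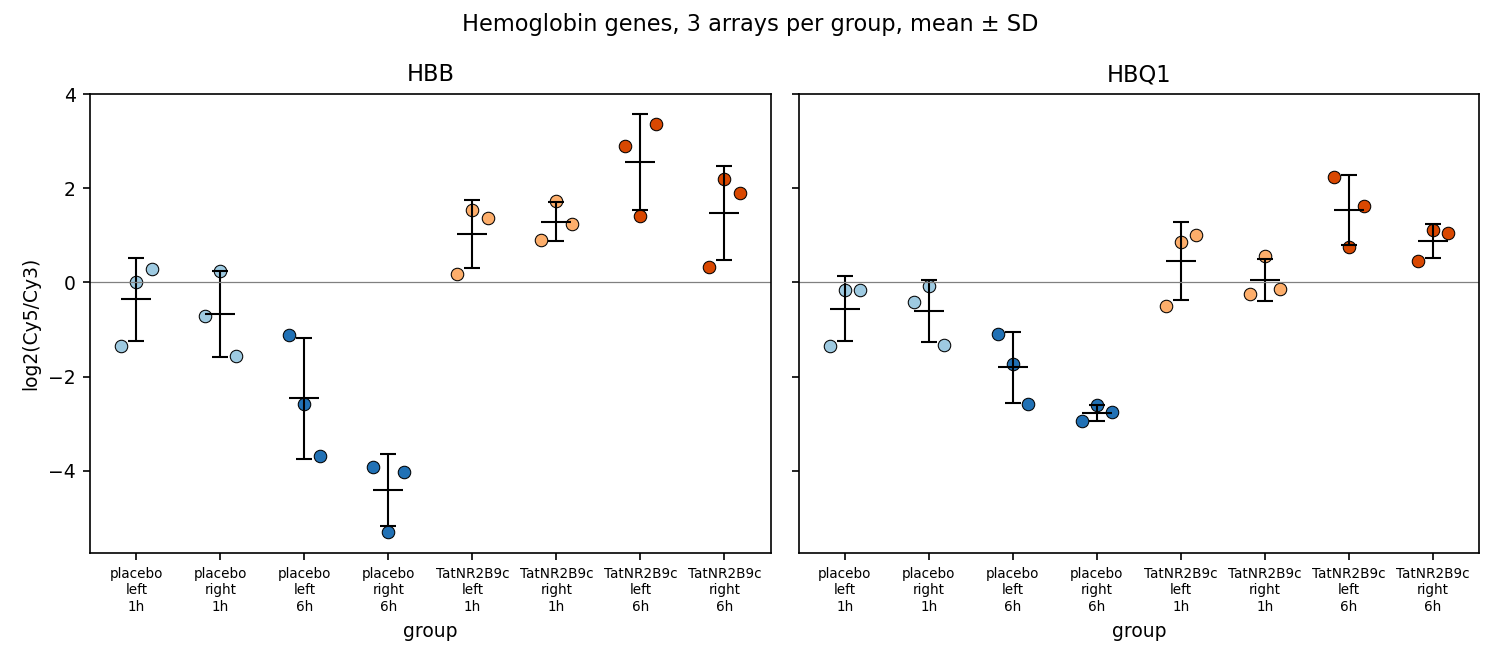
Log2 ratio of sample over reference for HBB and HBQ1 on each array (vertical axis) by group (horizontal axis), with points for the 3 arrays of a group and bars for mean and SD. At 6 h in right cortex, HBB was at −4.42 ± 0.77 under placebo and 1.47 ± 1.00 under TatNR2B9c.

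Neuronal genes lay lower in the same comparison. Ion channels were at −0.41 (adjusted p = 0.000142; 3 fell) and the AMPA list at −0.41 (adjusted p = 0.0076; 1 fell, 2 adjusted over the list alone). The NMDA list was at −0.32 (adjusted p = 0.00991; 0 fell) and neuron markers at −0.44 (adjusted p = 0.0076; 0 fell), the last pair at 0.12 and 0.21 at equal spread. With an estimated correlation the adjusted p was again 0.906. FGF14, a fibroblast growth factor homolog that binds sodium channels, fell by 1.62 (SE 0.19, adjusted p = 0.000387), with 2 of 3 TatNR2B9c arrays well above background. ANKRD5, an ankyrin repeat protein, fell by 3.99 (SE 0.47, adjusted p = 0.000387) from 4.08 ± 0.90 to 0.09 ± 0.22, with 1 of 3 TatNR2B9c arrays well above background. IDS, a lysosomal sulfatase, rose 4.6-fold (2.20, SE 0.28, adjusted p = 0.000485). In limma 428 genes were higher and 251 lower (3293 unadjusted), 211 and 66 by at least 2-fold, and 30.2% of genes had groups apart.

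Campaign and treatment cannot be told apart here either. Scaling mattered, since the count was 9 higher and 5 lower with processed signals, 10 and 13 in the series matrix and 32 and 456 under median centring. It was 493 and 787 in Cy5 alone, and 0 at equal spread (628 unadjusted), where HBB was at 3.49. HBB and HBQ1 kept their sign in each setting run and passed except at equal spread and under median centring (HBB 4.20, HBQ1 1.96; adjusted p from all settings up to 1). FGF14 (−1.65) and IDS (2.06) did not pass in either processed form, and equal spread ended these calls (−0.80 and 1.65) and that of ANKRD5 (−2.14). At equal spread ion channels were at −0.026, the AMPA list at −0.053, ribosomal proteins at 0.14, lymphocyte markers at 0.21, endothelial markers at 0.23 and meningeal markers at 0.18. In Cy5 alone ion channels were at −0.12, the AMPA list at −0.085, the NMDA list at −0.035, neuron markers at −0.31, lymphocyte markers at 0.09, endothelial markers at 0.28 and meningeal markers at 0.22. None of these passed, nor lymphocyte markers with processed signals, in the series matrix (both 0.34), under median centring (0.25) or without background subtraction (0.57). The total was 316 without placebo right 6 h array 1, 344 without array 2, 327 without array 3, 396 without TatNR2B9c right 6 h array 2 and 168 without TatNR2B9c array 3. Without TatNR2B9c array 3 endothelial markers (0.42), lymphocyte markers (0.57), the NMDA list (−0.18) and neuron markers (−0.17) did not pass. The same held for endothelial markers without placebo array 2 (0.49), for lymphocyte (0.58) and neuron markers (−0.37) without placebo array 3, and for meningeal markers without TatNR2B9c array 1 (0.71).

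In the non-ischemic cortex at 1 h, lists of neuronal genes also lay higher under TatNR2B9c. Neuron markers were higher by a median of 0.98 (adjusted p = 5.73e-11; 3 of 28 rose, 14 adjusted over the list alone) and the NMDA list by 0.51 (adjusted p = 3.7e-05; 2 of 29 rose, 6 adjusted over the list alone), with −2.61 and −1.88 under median centring and −0.19 for neuron markers in Cy5 alone. Ion channels were higher by 0.32 (adjusted p = 0.000493; 2 rose, 4 adjusted over the list alone), with −0.27 under median centring, and the adjusted p of these lists was 0.906 with an estimated correlation. ZFYVE19 rose by 3.57 (SE 0.47, adjusted p = 0.00174) and SLC32A1, the vesicular transporter of GABA, by 3.23 (SE 0.52, adjusted p = 0.00607), each with 2 of 3 placebo arrays well above background. ZFYVE19 was at 4.20 without placebo array 2 and 2.72 without placebo array 3, and SLC32A1 at 4.02 without TatNR2B9c array 3. In limma 162 genes were higher and 6 lower (1676 unadjusted), and 17.4% of genes had groups apart.

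The balance of higher and lower genes depended on the scaling, as 519 genes were higher and 1402 lower with processed signals, 499 and 1420 in the series matrix, 4051 and 8242 under median centring, 1513 and 1925 in Cy5 alone and 1236 and 444 at equal spread. Fitted on these groups alone limma called 0 genes (1585 unadjusted), with scan day as a random block 48 higher and 1 lower, and without the weak-reference arrays 21 and 1. The total was 48 without placebo left 1 h array 1, 51 without placebo array 3, 19 without TatNR2B9c left 1 h array 1 and 14 without TatNR2B9c array 2. SLC32A1 did not pass without TatNR2B9c array 1 or 2 (adjusted p up to 0.054), nor ion channels without placebo array 1 (0.16). Without the weak-reference arrays the NMDA list (0.18), ion channels (0.09) and SLC32A1 (3.35) did not pass, nor the NMDA list (0.19) and SLC32A1 (0.59) in Cy5 alone, nor either gene on these groups alone.

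At 6 h hemoglobin transcripts were higher under TatNR2B9c in the non-ischemic cortex too. HBB rose 32.7-fold (log2 5.03, SE 0.69, adjusted p = 0.00031) and HBQ1 by 3.35 (SE 0.48, adjusted p = 0.000333; further probes −0.20 and 3.35). HBB was at 5.70 without placebo left 6 h array 1 and 4.42 without placebo array 3. Neutrophil and red cell markers were higher by a median of 0.50 (adjusted p = 0.00138; 6 rose, and 8 rose and 1 fell adjusted over the list alone), and lymphocyte markers by 0.49 (adjusted p = 0.0149; 6 rose and 1 fell). Among the lower groups, ion channels were at −0.90 (adjusted p = 8.17e-06; 22 of 43 fell, 25 adjusted over the list alone) and the AMPA list at −0.89 (adjusted p = 0.00114; 7 of 16 fell). Neuron markers were at −0.69 (adjusted p = 0.0104; 6 fell), the NMDA list at −0.57 (adjusted p = 0.00398; 9 fell, 10 adjusted over the list alone) and oligodendrocyte markers at −1.02 (adjusted p = 0.00868; 5 fell). At equal spread neuron markers were at 0.39, the NMDA list at 0.05, ion channels at −0.023, the AMPA list at −0.16, oligodendrocyte markers at −0.37 and lymphocyte markers at 0.27. In Cy5 alone the NMDA list was at −0.16, neuron markers at −0.31 and oligodendrocyte markers at −0.95, and the tests of the AMPA and ion channel lists turned. None of these passed. With an estimated correlation the adjusted p was 0.906 for each.

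Within those lists DLG4, which encodes PSD-95 itself (rheMac2 chromosome 16, 6917708 to 6917767), fell by 1.25 (SE 0.24, adjusted p = 0.00177), and NOS1, the neuronal nitric oxide synthase bound to it, fell by 0.57 (SE 0.17, adjusted p = 0.0189). ANKRD5 fell by 4.12 (SE 0.47, adjusted p = 8.9e-05), with 2 of 3 TatNR2B9c arrays well above background. In limma 1707 genes were higher and 2165 lower (5916 unadjusted), 787 and 730 by at least 2-fold, and 33.5% of genes had groups apart.

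Campaign and treatment cannot be told apart. The count was 9 higher and 19 lower with processed signals, 9 and 20 in the series matrix, 609 and 2417 under median centring, 797 and 1827 in Cy5 alone, 1 and 2 fitted on these groups alone and 1 and 0 at equal spread. HBB, HBQ1, DLG4 and NOS1 did not pass in the last 2 settings. On these groups alone their differences were the same, with fewer arrays for the spread, while at equal spread they were 3.50, 2.25, −0.30 and −0.26, and ANKRD5 (−2.04) did not pass. HBB (3.07) and HBQ1 (1.40) did not pass under median centring. DLG4 (−0.87) and NOS1 (−0.62) did not pass in either processed form, nor NOS1 in Cy5 alone (−0.45) or with array weights (−0.53). The total was 2285 without placebo left 6 h array 1, 2561 without placebo array 3, 2041 without TatNR2B9c left 6 h array 1 and 2411 without TatNR2B9c array 3. NOS1 did not pass without placebo array 1 or TatNR2B9c array 1 (adjusted p up to 0.103), nor oligodendrocyte markers (−0.61) without TatNR2B9c array 3.

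Between 1 h and 6 h after placebo, transcripts of neurons and their receptors and channels were higher at the later time in the ischemic cortex, and those of lymphocytes lower. Neuron markers were higher by a median of 2.08 (adjusted p = 4.08e-08; 22 of 28 rose, 24 adjusted over the list alone), with 0.10 in Cy5 alone, −0.045 at equal spread and −0.92 under median centring. The AMPA list was higher by 1.77 (adjusted p = 3.7e-05; 12 of 16 rose, 14 adjusted over the list alone). Ion channels were higher by 1.71 (adjusted p = 7.71e-12; 34 of 43 rose) and the NMDA list by 1.58 (adjusted p = 1.55e-06; 21 of 29 rose and 1 fell, 23 and 1 adjusted over the list alone). GABA receptors were higher by 1.59 (adjusted p = 0.000264; 11 of 12 rose) and oligodendrocyte markers by 1.15 (adjusted p = 0.0148; 8 of 18 rose), with −0.25 and −0.93 in Cy5 alone and −1.40 for the latter under median centring and −0.11 at equal spread. Lymphocyte markers were at −0.81 (adjusted p = 0.00188; 8 of 11 fell), with a turned test in Cy5 alone. The adjusted p was 0.906 with an estimated correlation for these lists.

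**Figure D3:**
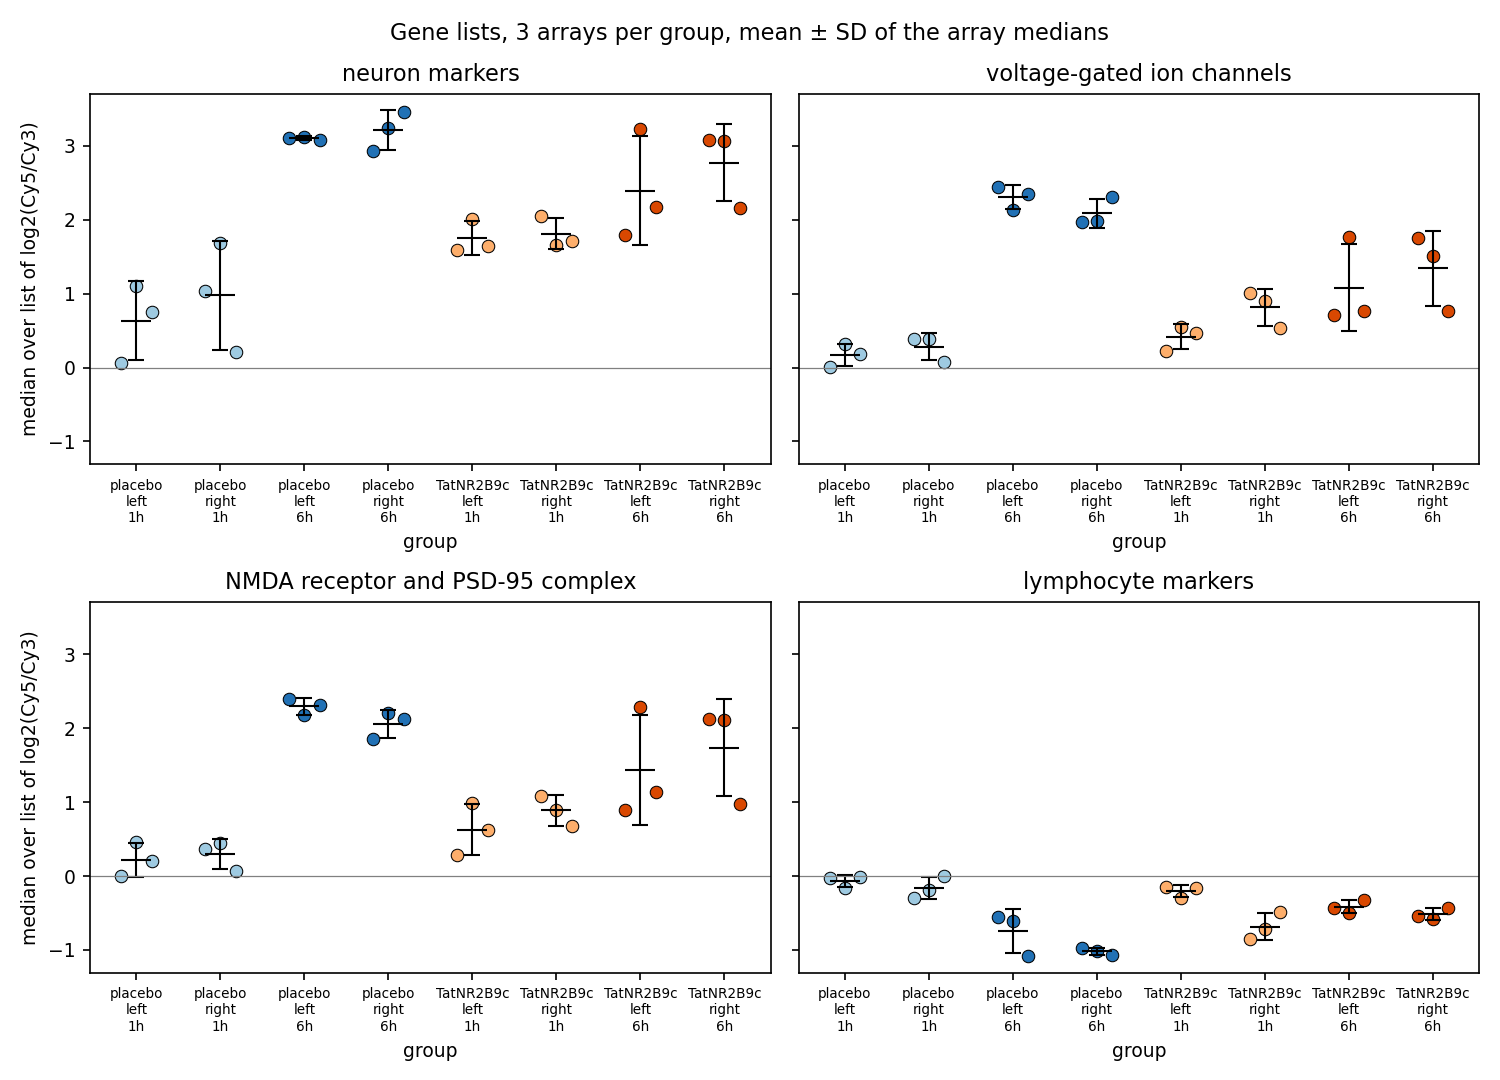
Median log2 ratio of sample over reference of 4 gene lists (neuron markers, voltage-gated ion channels, NMDA receptor and PSD-95 complex, lymphocyte markers) on each array (vertical axis) by group (horizontal axis), with points for the 3 arrays of a group and bars for mean and SD. Between 1 h and 6 h in placebo right cortex the neuron list differed by a median of 2.08 (−0.92 under median centring and −0.045 at equal spread) and the lymphocyte list by −0.81 (test turned in Cy5 alone).

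ICAM5, an adhesion molecule of telencephalic dendrites (rheMac2 chromosome 19, 10109477 to 10109536), rose 18.4-fold in placebo right cortex (log2 4.20, SE 0.55, adjusted p = 2.59e-05), from −0.56 ± 0.43 to 3.65 ± 0.62 (SD, n = 3). SLC32A1 rose by 3.94 (SE 0.52, adjusted p = 2.57e-05) and GRIA3, an AMPA receptor subunit, by 3.92 (SE 0.50, adjusted p = 1.99e-05; its further probes 0.17 to 2.61). DLG4 rose by 1.87 (SE 0.24, adjusted p = 2.19e-05) and GRIN2B, which encodes NR2B (chromosome 11, 13928782 to 13928841), by 1.95 (SE 0.52, adjusted p = 0.00638) with 1 of 3 of the 1 h arrays well above background. HBB fell by 3.74 (SE 0.69, adjusted p = 0.000412). In limma 3429 genes were higher and 3089 lower (7821 unadjusted), 1822 and 1780 by at least 2-fold, and 59.7% of genes had groups apart.

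Time and campaign cannot be told apart. Counts were 916 higher and 1441 lower with processed signals, 894 and 1469 in the series matrix and 3785 and 7647 under median centring, and 326 and 414 at equal spread. Of the genes named only ICAM5 passed in all settings other than the arrays left out. At equal spread SLC32A1 (7.51), GRIA3 (0.89), GRIN2B (1.01) and HBB (−0.26) did not pass, nor in Cy5 alone SLC32A1 (0.72) and GRIN2B (1.33), nor in either processed form DLG4 (1.09). In Cy5 alone the AMPA list was at 0.18 and the NMDA list at 0.26, and at equal spread they were at 0.14 and 0.094 and GABA receptors at 0.16, none passing. Under median centring GABA receptors were at 0.23 and lymphocyte markers at −0.58, and in the processed forms oligodendrocyte markers were at 0.21, none passing. Without placebo right 1 h array 3 the total was 4103. Oligodendrocyte markers lost the call without placebo right 6 h array 3 (0.85).

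In the non-ischemic cortex of placebo animals, neuronal and oligodendrocyte lists were also higher at 6 h and lymphocyte markers lower. Neuron markers were higher at 6 h by 2.39 (adjusted p = 4.55e-07; 25 of 28 rose) and ion channels by 2.20 (adjusted p = 8.65e-11; 38 of 43 rose, 39 adjusted over the list alone). The AMPA list was higher by 2.07 (adjusted p = 1.58e-05; 15 of 16 rose) and the NMDA list by 1.96 (adjusted p = 3.34e-06; 24 rose and 1 fell), beside a median of 0.11 over all genes. Under median centring neuron markers were at −1.14, the NMDA list at −0.31 and GABA receptors at −0.10. GABA receptors (2.11, adjusted p = 0.000665; 11 of 12 rose) and oligodendrocyte markers (1.54, adjusted p = 0.0172; 11 rose and 1 fell) were higher, with −0.48 and −0.37 in Cy5 alone and −1.18 for the latter under median centring. Lymphocyte markers were at −0.69 (adjusted p = 0.00473; 8 of 11 fell), with a turned test in Cy5 alone. The adjusted p was 0.906 with an estimated correlation. SLC32A1 rose by 4.89 (SE 0.52, adjusted p = 2.95e-06), ICAM5 by 4.85 (SE 0.55, adjusted p = 4.59e-06) and SLC8A2 by 4.58 (SE 0.34, adjusted p = 4.88e-07). GRIN2B rose by 2.52 (adjusted p = 0.000604) and DLG4 by 2.38 (adjusted p = 2.42e-06). SLC32A1, SLC8A2 and DLG4 were well above background on 2 of 3 arrays at 1 h, and ICAM5 was at 4.18 without 1 h array 3.

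In placebo left cortex limma called 4944 genes higher and 3705 lower (9493 unadjusted), 2694 and 2135 by at least 2-fold, and 64% of genes had groups apart. Again time and campaign cannot be told apart, and the counts were 1805 higher and 2901 lower with processed signals, 1775 and 2946 in the series matrix and 4146 and 8015 under median centring. In Cy5 alone neuron markers were at 0.13, ion channels at 0.12, the AMPA list at 0.07 and the NMDA list at 0.11, with SLC32A1 at 0.52, SLC8A2 at 0.78 and GRIN2B at 0.99, none passing. At equal spread neuron markers (0.58), GABA receptors (0.57), oligodendrocyte (0.42) and lymphocyte markers (−0.28) did not pass. In the 2 processed forms DLG4 was at 1.41 and 1.42 and lymphocyte markers at −1.19 and −1.21, none passing, nor lymphocyte markers under median centring (−0.71), nor oligodendrocyte markers (0.89) without the weak-reference arrays.

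Under TatNR2B9c the times shared a scan campaign, and the neuronal lists lay higher at 6 h in both hemispheres. In the ischemic cortex, ion channels were higher by a median of 0.65, with 43 of 43 members above 0 (adjusted p = 1.07e-08; 0 rose over all genes, 12 adjusted over the list alone). Neuron markers were higher by 0.81 (adjusted p = 0.000188; 0 rose, 8 adjusted over the list alone), the NMDA list by 0.62 (adjusted p = 3.34e-06; 0 rose, 8 adjusted over the list alone) and the AMPA list by 0.52 (adjusted p = 0.00263; 0 rose, 1 adjusted over the list alone). In Cy5 alone the medians were −0.06, −0.14, 0.09 and −0.12, and the tests of all 4 turned, and neuron markers were at −0.07 at equal spread (the AMPA list 0.12, not passing) and −0.24 under median centring. The adjusted p was 0.906 with an estimated correlation. PYY, a peptide hormone of the NPY family (rheMac2 chromosome 16, 54028955 to 54029014), rose by 2.23 and CPLX1 by 1.77. Both had an adjusted p of 0.0493. In limma 17 genes were higher and 2 lower (3083 unadjusted), 10 of the former by at least 2-fold, and 27.8% of genes had groups apart.

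With slide as a block limma called 0 genes (990 unadjusted), with scan day as a block 4 higher and 0 lower. PYY and CPLX1 passed in 6 and 4 of 15 settings other than the arrays left out, and in neither of these, with differences under slide and day of 2.09 and 2.13 for PYY and 1.65 and 1.52 for CPLX1. Median centring gave 0.86 and 0.45 and Cy5 alone 1.58 and 0.87, and equal spread gave 1.07 for CPLX1. Slide 9 held 1 array of each time and day 4 held 1 array at 6 h and 3 at 1 h, too few to test single genes. With slide as a block ion channels were at 0.29, neuron markers at 0.65, the NMDA list at 0.56 and the AMPA list at 0.31 (adjusted p = 0.0675), and with scan day at 0.19 (adjusted p = 0.0957), 0.44 (0.0664), 0.46 and 0.16 (0.131). Within slide 9 and day 4 the medians were 0.28 and 0.12 for ion channels, 0.34 and 0.21 for neuron markers, 0.41 and 0.35 for the NMDA list and 0.42 and 0.13 for the AMPA list. Without TatNR2B9c right 1 h arrays 1, 2 and 3 the total was 0, 8 and 0. Without 6 h arrays 1, 2 and 3 it was 2, 0 and 302, and without array 3 time and scan day coincided. The total was 2 with processed signals and 0 in Cy5 alone (2084 unadjusted).

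In the non-ischemic cortex under TatNR2B9c, ion channels were higher at 6 h by 0.61 (adjusted p = 4.18e-12; 0 rose, 1 adjusted over the list alone), neuron markers by 0.62 (adjusted p = 0.00104; 0). The AMPA list was higher by 0.57 (adjusted p = 0.000472; 0 rose, 2 adjusted over the list alone) and the NMDA list by 0.39 (adjusted p = 0.000151; 0). At equal spread ion channels (0.006) did not pass and the other lists turned (neuron markers −1.18, AMPA −0.06, NMDA −0.16), in Cy5 alone they were at −0.20, −0.19, −0.23 and −0.21, and with processed signals at −0.09, −0.09, −0.18 and −0.07. In the series matrix they were at −0.07, −0.09, −0.18 and −0.07, and under median centring neuron markers were at −0.06 and the NMDA list at −0.007. Immediate early genes were higher by 0.36 (adjusted p = 0.000472; 0 rose, 1 adjusted over the list alone). Proteasome subunits lay at −0.34 over 27 genes (adjusted p = 0.000723; 0). With an estimated correlation the adjusted p was 0.906 for these lists. Of single genes limma called 0 (2576 unadjusted), and 17.5% had groups apart.

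Without TatNR2B9c left 6 h array 3 limma called 765 genes there, 175 higher and 590 lower, and immediate early genes were at 0.03 (adjusted p = 0.317). Proteasome subunits were at −0.19 without 6 h array 1 and −0.20 in either processed form, and did not pass. With slide as a block ion channels were at 0.37, neuron markers at 0.25, the AMPA list at 0.40, the NMDA list at 0.24, immediate early genes at 0.89 and proteasome at −0.20. With scan day as a block they were at 0.21, 0.12, 0.27, 0.17, 0.73 and −0.34, where neuron markers did not pass (adjusted p = 0.214). Both blocks called 0 genes in limma (566 with slide and 664 with day unadjusted), and slide 9 and day 4 held 1 array at 6 h. Within slide 9 and day 4, immediate early genes were at 1.48 and 1.16, ion channels at 0.32 and 0.29, neuron markers at 0.54 and 0.20 and proteasome at 0.02 and −0.16.

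Whether treatment changed the time course in ischemic cortex was tested as an interaction of treatment and time. Lists of neuronal genes lay lower in this difference, with few members past the threshold. Neuron markers were at −1.32 (adjusted p = 1.55e-06; 1 fell), with 0.46 under median centring, and GABA receptors at −1.04 (adjusted p = 0.00164). Ion channels were at −0.98 (adjusted p = 7.09e-08; 3 fell, 6 adjusted over the list alone), the AMPA list at −0.87 (adjusted p = 0.00102; 1 fell, 4 adjusted over the list alone) and the NMDA list at −0.80 (adjusted p = 0.00104). Lists of blood and vessel cells lay on the other side, with neutrophil and red cell markers at 0.96 (adjusted p = 0.00914; 3 rose), and lymphocyte markers at 0.92 (adjusted p = 0.000484; 8 rose adjusted over the list alone). Endothelial markers were at 0.70 (adjusted p = 0.0163). With an estimated correlation the adjusted p was 0.906 for each. SOD2, the superoxide dismutase of mitochondria, was higher by 1.8 (SE 0.30, adjusted p = 0.00585) and HBB by 3.92 (SE 0.98, adjusted p = 0.0368). RND1, a small GTPase of neurons, was at −2.60 (SE 0.51, adjusted p = 0.0121). In limma 430 genes were higher and 139 lower (3462 unadjusted), 370 and 93 by at least 2-fold.

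The same campaigns carry this interaction. Counts were 12 higher and 1 lower with processed signals, 14 and 1 in the series matrix, 3 and 14 under median centring, 1 and 0 at equal spread, 48 and 206 in Cy5 alone and 144 and 22 without the weak-reference arrays. The total was 301 and 114 without placebo right 1 h arrays 1 and 3, 297 and 178 without placebo 6 h arrays 1 and 3, 111 and 166 without TatNR2B9c 1 h arrays 1 and 2, and 990 and 124 without TatNR2B9c 6 h arrays 1 and 3. HBB passed with 1 of the 12 arrays left out (adjusted p up to 0.115). At equal spread neuron markers were at −0.12, GABA receptors at −0.12, the AMPA list at −0.065, the NMDA list at −0.047, neutrophil and red cell markers at 0.21 and endothelial markers at 0.015, none passing. In Cy5 alone neuron markers (−0.26), GABA receptors (−0.33), neutrophil and red cell (0.34), lymphocyte (0.44) and endothelial markers (0.19) did not pass. Under median centring the NMDA list (−0.24), GABA receptors (−0.27), neutrophil and red cell (0.35), lymphocyte (0.19) and endothelial markers (0.39) did not pass, nor endothelial markers with processed signals (0.86). SOD2, HBB and RND1 did not pass with processed signals, in the series matrix, under median centring (0.16, 7.16 and −1.23) or at equal spread (1.52, 0.08 and −4.28), nor SOD2 in Cy5 alone (0.50).

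The genes of the complex that the peptide targets did not pass the test between the ischemic and the non-ischemic cortex in any of the 4 groups of animals. DLG4 was at 0.17 and −0.34 under placebo at 1 h and 6 h and at −0.06 and 0.26 under TatNR2B9c, GRIN2B at 0.36, −0.21, 0.22 and 0.45, and NOS1 at 0.08, −0.50, −0.43 and 0.22. Between treatments in ischemic cortex, DLG4 was at 0.15 (adjusted p = 0.845) at 1 h and −0.65 (adjusted p = 0.127) at 6 h, where it passed under median centring (−1.46), in Cy5 alone (−1.37) and without TatNR2B9c array 2 (−0.99). Over time under TatNR2B9c in ischemic cortex DLG4 was at 1.07 (adjusted p = 0.068), and passed with the replicate number as a block (1.07), with array weights (1.15) and without 6 h array 3 (1.29). In treatment by time it was at −0.80 (adjusted p = 0.182), and passed without TatNR2B9c 6 h array 2 (−1.14).

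Across the 15 comparisons, 4 of the 25 lists never passed. RNA polymerase II and general transcription factors (47 genes) had medians from −0.20 to 0.17 (smallest adjusted p 0.184), and the endoplasmic reticulum and integrated stress response (21 genes) from −0.25 to 0.14 (0.21). For hypoxia-inducible targets (28 genes) they ran from −0.13 to 0.18 (0.0921) and neurotrophic factors and receptors (16 genes) from −0.10 to 0.21 (0.435). Calls lost in many settings were those of NRF2 targets and metallothioneins right against left in placebo at 1 h (−0.12 over 17 genes, adjusted p = 0.0483; 0.22 in Cy5 alone), microglia (−0.60, adjusted p = 0.0451; 0.037 at equal spread) and endothelial markers (−0.39, adjusted p = 0.0334; −0.02 in Cy5 alone) over time in placebo right cortex, microglia markers in treatment by time (0.67, adjusted p = 0.0218), and the 12 reference genes there (−0.52, adjusted p = 0.033; 1.02 under median centring), which passed in 6, 5, 12, 11 and 9 of 17 settings. The apoptosis and p53 list in left cortex at 6 h (0.39 over 26 genes, adjusted p = 0.0406; −0.13 under median centring) passed in 12 of 16, and oxidative phosphorylation over time under TatNR2B9c on the left (−0.22 over 47 genes, adjusted p = 0.0242) in 11 of 16. In treatment by hemisphere at 1 h, lymphocyte markers (−0.34, adjusted p = 0.0285) passed in 12 of 17 and immediate early genes (0.17, adjusted p = 0.0367) were lost without any 1 of 6 arrays. Of 375 tests of the 25 lists 108 passed, 71 higher and 37 lower, none of which held with an estimated correlation (adjusted p = 0.906, 6 unadjusted). Over all comparisons 752 of 9555 list members passed over all genes and 851 adjusted over the list alone.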

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

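The tests of compressed log ratios, weak reference signal, reference channel, blood and other splits of the arrays were chosen only after the result was seen, as were array weights, equal spread, Cy5 alone and the fit without weak-reference arrays, whereas the test on the tissue over time was fixed before.

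Treatment by time in right cortex stood out because the interaction test itself passed, for 569 genes and 10 gene lists. Compression of the log ratios by different amounts in the scan campaigns may account for it. Across genes the difference correlated at −0.79 with the mean log ratio over the 12 left cortex arrays, which lie outside the comparison, though genes are not independent replicates. Within 1 campaign, right against left in placebo at 1 h also correlated, at 0.57, with the mean over the 12 TatNR2B9c arrays. The correlation thus cannot tell compression between campaigns from other causes. The weak reference signal of the placebo 1 h arrays stays open as well, as 66.3% of these genes kept their sign in Cy5 alone. Of 100 splits of the arrays, drawn with a fixed seed, 1 gave as many genes, the real one (highest other 279). The others mixed campaigns within groups, so chance stays open. As many lists came from 18 (highest other 13), so chance is not excluded. A difference in the course of the stroke between treatments stays open, untested, because treatment and campaign cannot be told apart.

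The genes passing between 6 h and 1 h placebo arrays, in both hemispheres, were the most of any comparison. Their change in right cortex correlated across genes at 0.79 with the mean log ratio over the 12 TatNR2B9c arrays, which compression between campaigns predicts. In Cy5 alone 63.8% kept their sign in right and 55.4% in left cortex, while Cy3 alone gave 3699 genes in right and 4780 in left cortex and Cy5 alone 3962 and 2320, so the weak reference signal of the placebo 1 h arrays may add to it. A change of the tissue over time predicts the same direction in TatNR2B9c animals, scanned in 1 campaign, where 87.3% kept the sign with a median of 0.38 in the placebo direction against 1.09 under placebo. This cannot be told apart from a ratio scale that differs between days, which would keep the sign too.

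The hemoglobin genes higher under TatNR2B9c at 6 h are the third pattern. A difference in the reference channel is argued against by HBB in Cy5 alone, which differed by 4.24 (SE 0.44, adjusted p = 5.13e-05) in right cortex. Compression is argued against by the lowest HBB log ratio of the TatNR2B9c right 6 h arrays, 0.33, against a highest of −3.93 under placebo, since scaling turns no sign. A difference in blood between the samples stays open. From 1 h to 6 h right HBB went from −0.68 to −4.42 under placebo (left −0.36 to −2.47). Under TatNR2B9c it was 1.29 and 1.47 (left 1.03 and 2.56). White cell genes (24) had a median difference of 0.41 (quartiles 0.14 and 1.22, 0 passed in limma). In left cortex it was 0.48, and 8 rose and 1 fell. At 1 h HBB did not pass (right 1.97, left 1.39, adjusted p = 0.19 and 0.507 in limma, 0.12 and −0.41 in Cy5 alone). Blood in the tissue and campaign cannot be told apart from treatment at 6 h.

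Treatment by hemisphere at 1 h passed the interaction test for 3 lists, and at 6 h for 5 lists, with 0 genes in limma at each time (285 and 678 at unadjusted p under 0.05). With an estimated correlation 0 of these lists passed (adjusted p = 0.906), and 8 and 7 of 10 splits of the arrays gave as many lists.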

How the results depend on the processing

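Array weights, equal spread, Cy5 alone and the fit without the 3 weak-reference arrays were tests chosen only after the result was seen. Apart from the arrays left out, 186 counts of genes stayed within 1.5 times and 61 moved, 1447 list calls kept direction and side of the threshold, 253 kept only the direction and 78 turned. Of the named genes 4572 values were the same, 772 weaker, 27 stronger and 102 turned. With arrays left out, 73 counts stayed and 35 moved, 609 list calls were the same, 139 weaker and 8 turned, and 2021 gene values were the same, 466 weaker and 21 stronger. Against 108 list calls, settings with a preset correlation gave 67 in Cy5 alone and 72 to 124 otherwise. Of the 108 themselves, 30 passed in the same direction in Cy5 alone, 40 at equal spread, 63 with median centring and 83 or more in the others, and with an estimated correlation 0 passed (6 at unadjusted p under 0.05 in limma). The share of probes above background kept its side of the test in all alternatives, as 3 against 3 arrays must. Signal over background was 1.18 to 1.5 in Cy3 on the weak-reference arrays and 1.3 and 1.2 in Cy5 on TatNR2B9c left 1 h arrays 1 and 2, and the log ratio of a probe near background in either channel depends on the background taken off. Sizes of calls that were kept also moved by over 1.5 times in some scalings. Quantile scaling of intensities left the log ratios as they were and tests nothing. Below, the cause of each shift was not tested, except that fits on fewer arrays have fewer degrees of freedom.

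The replicate number as a block gave 252 genes for time under TatNR2B9c on the right against 19. Deviations of the same-numbered arrays correlated there at 0.24, 0 and 0.28, so the numbers are not shown to pair animals across times. Among genes and lists named in the text the block changed DLG4 there (1.07, now passing) and no other call. In all, 105 of 108 list calls and 193 of 199 gene calls passed with the block too. The spread of right-left differences passed in no alternative (smallest exact permutation p 0.1), with differences from −0.46 to 0.03 at 1 h and −0.14 to 0.12 at 6 h, arrays left out included.

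Counts for treatment in right cortex at 1 h were 945 with processed signals, 947 in the series matrix, 10696 with median centring, 2073 with array weights, 169 after equal spread, and 2716 in Cy5 alone. They were 54 without weak-reference arrays, 42 on these groups alone and 94 with scan day, against 256. At 6 h on the right they were 14, 23, 1107 with weights, 0 after equal spread (628 at unadjusted p under 0.05 in limma) and 1280 in Cy5 alone, against 679. In left cortex at 1 h they were 1921 with processed signals, 1919 in the matrix, 12293 with median centring, 411 with weights, 1680 after equal spread, and 3438 in Cy5 alone. They were 22 without weak-reference arrays, 0 on these groups alone (1585 at unadjusted p under 0.05) and 49 with scan day, against 168. At 6 h on the left they were 28, 29, 3 on these groups alone and 1 after equal spread, against 3872. For time in placebo right cortex they were 2357, 2363, 11432 with median centring, 740 after equal spread and 3962 in Cy5 alone, against 6518. On the left they were 4706, 4721, 2087 after equal spread, 2320 in Cy5 alone and 4074 without weak-reference arrays, against 8649. For time under TatNR2B9c on the right they were 2 with processed signals, 3 in the matrix, 4 with no background subtraction, 11 with no filter, 4 with scan day and 2068 with weights. They were 0 with median centring, the filter in both channels, every probe by itself, these groups alone, slide, equal spread and Cy5 alone, against 19. On the left median centring gave 1 against 0. For treatment by time they were 13, 15, 17 with median centring, 1 after equal spread, 1510 with weights, 254 in Cy5 alone and 166 without weak-reference arrays, against 569. No filter gave 1 for right against left in placebo at 6 h and weights gave 7 under TatNR2B9c at 1 h, each against 0.

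List medians whose test turned were as follows. With processed signals and in the series matrix, left cortex over time under TatNR2B9c gave −0.177 and −0.176 for the AMPA list and −0.085 and −0.073 for ion channels, and ion channels right against left under TatNR2B9c at 1 h −0.27 and −0.21. Median centring gave −1.14 (neuron) and −1.18 (oligodendrocyte) over time in placebo left and −1.40 (oligodendrocyte) in placebo right. For treatment it gave −1.88 (NMDA) and −2.61 (neuron) on the left at 1 h, −1.10 (NMDA), −3.43 (ribosomal), −0.26 (lymphocyte) and −1.71 (neuron) on the right at 1 h, and −0.79 (ribosomal) at 6 h. It gave −0.13 (NMDA) and −0.36 (neuron) right against left in placebo at 1 h, and 1.02 (reference genes) for treatment by time. Equal spread gave −0.063 (AMPA), −0.16 (NMDA) and −1.18 (neuron) over time under TatNR2B9c on the left, −0.065 (neuron) on the right and −0.064 (endothelial) in placebo right. For treatment it gave 0.045 (NMDA) and 0.39 (neuron) on the left at 6 h and 0.12 and 0.21 on the right, with −0.071 for ion channels right against left under TatNR2B9c at 1 h. Slide as a block gave 0.046 for inflammatory genes in treatment by hemisphere at 6 h. Without weak-reference arrays ribosomal proteins were at 0.17 and NRF2 targets at 0.29 right against left in placebo at 1 h, and ribosomal proteins at −0.27 in treatment by hemisphere at 1 h.

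Cy5 alone gave −0.23 (AMPA), −0.21 (NMDA), −0.19 (neuron) and −0.20 (ion channels) over time under TatNR2B9c on the left, and −0.12, 0.089, −0.14 and −0.064 on the right. In placebo left it gave −0.48 (GABA), −0.002 (lymphocyte) and −0.37 (oligodendrocyte), and in placebo right −0.25, −0.008 and −0.93, with −0.018 (endothelial). Treatment on the left at 6 h gave −0.006 (AMPA) and −0.13 (ion channels), and right against left under TatNR2B9c at 1 h 0.005 (ion channels). In placebo at 1 h it gave −0.10 (NMDA), 0.091 (ribosomal), −0.10 (neuron), 0.22 (NRF2) and −0.11 (ion channels). In treatment by hemisphere it gave −0.13 (ribosomal, 1 h), −0.028 (AMPA, 6 h) and 0.03 (ion channels, 6 h), and GNG4 on the right at 1 h was at 0.39.

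With each array left out, counts ran from 17 to 205 for treatment on the right at 1 h and 168 to 999 at 6 h, 14 to 248 on the left at 1 h and 2041 to 5563 at 6 h. They ran from 4103 to 6461 for time in placebo right, 0 to 302 under TatNR2B9c on the right and 0 to 765 on the left (765 without left 6 h array 3). For others they were 0 to 3 for right against left in placebo at 6 h (3 without left array 2), 0 to 21 for treatment by hemisphere at 6 h (21 without TatNR2B9c left array 2) and 111 to 990 for treatment by time. The list medians that turned ran from −0.45 to 0.18 (inflammatory, TatNR2B9c 6 h), 0.025 to 0.775 (neuron, placebo 1 h), −0.51 to 0.11 (NRF2, placebo 1 h) and −0.64 to 0.073 (immediate early, placebo 6 h), all right against left. The 302, 765 and 3 came where time or side coincided with scan day.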

Other observations

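All splits, and the tests of the size of the right-left difference below, were chosen only after the result was seen.

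The size of the right-left difference of immediate early genes did not pass between 6 h and 1 h over the 25 lists, and had no common direction. The median right-left difference of the list in placebo animals 1, 2 and 3 was −0.05, −0.06 and 0.15 at 1 h and −0.49, −1.22 and 0.82 at 6 h. Under TatNR2B9c it was 0.11, 0.05 and 0.30 at 1 h and −0.25, 0.36 and −0.99 at 6 h. The size of the difference averaged 0.12 ± 0.10 (SD, n = 6) at 1 h and 0.69 ± 0.38 (n = 6) at 6 h (two-sided exact permutation p = 0.00433), and the adjusted p over the 25 lists was 0.108. Within placebo the exact permutation p was 0.1 and within TatNR2B9c 0.2. The arrays of an animal shared a slide except in placebo at 6 h. For NRF2 targets and metallothioneins the size differed by −0.30 (exact permutation p = 0.00866, adjusted p = 0.108), which did not pass either. The SD over all genes of the right-left difference was 0.54 ± 0.27 at 1 h and 0.47 ± 0.17 at 6 h (n = 6 and 6, exact permutation p = 0.602).

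For each comparison of 6 arrays there are 10 splits of 3 against 3, too few for a share under 0.05. Splits with as many genes as the real one numbered 1 for treatment in right cortex at 1 h (256 genes, highest other 0) and at 6 h (679, 1), 2 in left cortex at 1 h (168, 248) and 1 at 6 h (3872, 102), 1 for time in placebo right (6518, 0) and placebo left cortex (8649, 2), 1 under TatNR2B9c on the right (19, 0) and 10 on the left (0, 1). For treatment by hemisphere 10 of 10 gave as many at each time (0, highest other 0). For right against left, 10 gave as many as the real 0 in each group of animals, and the highest other was 1845 in placebo at 1 h, 4 at 6 h, 49 under TatNR2B9c at 1 h and 2730 at 6 h. The splits of 1845 and 2730 point to a structure of the samples: each set left arrays 1 and 3 and right array 3 against the rest, which in placebo at 1 h are the 3 weak-reference arrays. Among splits that part all 3 animals as the real one does, the highest were 0, 4, 0 and 5, and the others put both arrays of an animal on one side.

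Splits with as many lists numbered 6 for right against left in placebo at 1 h (7 lists, highest other 11; 8 among splits that part all animals), 10 at 6 h (4, 9; 9), 3 under TatNR2B9c at 1 h (6, 6; 6) and 3 at 6 h (8, 11; 7). They numbered 7 for treatment in right cortex at 1 h (7, 11), 3 at 6 h (9, 11), 5 in left cortex at 1 h (7, 11) and 4 at 6 h (11, 14). For time they numbered 6 in placebo right (9, 13), 9 in placebo left (7, 13), 2 under TatNR2B9c on the right (6, 7) and 5 on the left (9, 10), and for treatment by hemisphere 8 at 1 h (3, 9) and 7 at 6 h (5, 9).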
